A study of Sus scrofa with 15 samples.

How the data were processed

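Expression in pig backfat was measured on 15 arrays, each hybridized with 2 RNAs, 1 labelled with Cy3 and 1 with Cy5. Per the labels, total RNA was isolated from tissue kept in a stabilizing solution, amplified linearly and labelled with an amplification kit for 2 colours. The RNAs carried 10 labels, 1 for each of 2 breeds at each of 5 months, and each label was on 3 arrays. How many animals stood behind a label is not given in the sources used here.

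Per the file headers, the scanner files give the intensity of each spot and of its local background, not corrected for background, from fixed circles with the extreme pixels trimmed. Each of the 30 channels held 656 spots in 2 block rows of 4 block columns, with 82 spots to a block. Spots at the same place in the 4 block columns of a block row were treated as copies, since the lowest rank correlation between them was 0.995. Between the block rows the highest was 0.0907, apart from 12 positions at the start of each block, where the lowest was 0.972. Those 12 positions were read as controls from this pattern alone, because the files do not say what they hold, and they were left out. The remaining 140 probes had 4 spots each and are named by block row, spot row and spot column. The files do not pair these positions with genes, so the rule for named genes, which took probes with a gene name only, could not be applied. In its place, the 2 probes with the steepest rise and the 2 with the steepest fall among those called for a shared change over months were named, a rule chosen after the values were seen. The tests of gene lists were not run for the same reason.

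The value table deposited by the authors holds log2 ratios for 656 spots, with none given at the 96 control spots and 246 to 434 values for each array in the other positions. Its column medians on the log2 scale in the deposited table were -0.11, 0.0073, -0.15, 0.011 and -0.13 for Landrace months replicates 1 to 5. For Taihu months replicates 1 to 5 they were -0.29, 0.15, -0.17, -0.13 and 0.0036. For Taihu versus Landrace replicates 1 to 5 they were -0.0028, -0.044, -0.033, 0.012 and -0.22. In file order the table correlated with log2(Cy3/Cy5) of the scanner files at r between 0.350 and 0.592. With the blocks of the table read alternately from the 2 block rows, r rose to between 0.765 and 0.914. After a constant between 92.8 and 1626 was fitted and subtracted in each channel, r was 0.905 to 0.975 and the slope 0.927 to 1.09. The scale and the direction, Cy3 over Cy5, were read from this match. How the authors normalized and centred the table is not given in the sources used here, so its centring stays unknown. The table therefore served only as an alternative, with its sign turned.

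Median spot intensities were corrected for background with the normexp method (offset 50), turned into log2(Cy5/Cy3) and normalized by loess within each array, with control spots at weight 0. The 139 of 9840 spots marked by the scanner software were left out, and the remaining copies of a probe were averaged. No value remained for 2 probes on 1 array. Probes were kept where they exceeded local background by 2 background SD in at least 50% of channels, which all 140 did. R 4.3.3 and limma 3.58.1 were used throughout.

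Median signals of the channels ran from 690 to 2681 and median backgrounds from 99 to 564. Of the probes, 135 exceeded background in all 30 channels, and 78 exceeded the highest of 5 dim control positions in at least 50% of them. At least 1 spot reached the scanner maximum of 65535 on some array for 19 probes. The number of arrays limits the precision.

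Models were fitted to each probe with lmFit and moderated with eBayes, and p-values were adjusted by the Benjamini-Hochberg method, with calls at an adjusted p under 0.05. An additive model held a breed term, 4 month terms and a dye term (9 residual degrees of freedom). It tested the mean breed difference and, by a moderated F over the month terms, the change over months shared by both breeds. The full model held a term for each breed and month and a dye term (5 residual degrees of freedom). It tested the breed difference at single months, the change over months in each breed, 10 single steps between months and the dependence of the breed difference on month. Directions over months were taken from the slope of the month estimates. On all 5 breed arrays Landrace was Cy3 and Taihu Cy5, so the dye term rests on the 2 loops of month arrays, where each RNA was once in each dye. The comparisons, tests and most alternatives were chosen before the data were examined.

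Both models were tested on simulated data with the array noise of the full model and 140 probes, 20 runs each. For changes of 0.5 and 1 on the log2 scale, the mean breed test recovered 82.5% and 97.0% of changed probes. Recovery of breed differences at single months was 62.2% and 93.1%, and of the dependence on month 59.8% and 91.3%. For shared month changes it was 74.8% and 93.5%, for those in Landrace 53.3% and 90.2%, and for those in Taihu 73.4% and 94.2%. False calls made up 1.02% to 6.71% of calls. Each run gave 30 probes a breed difference that depended on month, while 78 probes were called for this in the data. The median residual SD of the additive model was 0.31 in the data, against 0.15 in the full model. Recovery by the mean breed and shared month tests is therefore likely to be lower in the data than simulated.

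Alternatives covered background correction, loess, scaling between arrays, filters on dim probes, the spot signal, marked spots, the dye term, variance moderation, array weights, the value table, parts of the arrays alone and each array left out in turn. Chosen after seeing the data were a filter on the dim control positions, leaving out probes with saturated spots, subtracting the dim control level, and giving the main counts without Taihu months replicate 5.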

Results

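Gene expression in backfat, the fat layer under the skin of the back, was compared between Landrace, a lean type of pig, and Taihu, a fat type, over 5 months of growth. The 15 arrays fell into 3 groups of 5. In the Taihu versus Landrace group, each replicate set the breeds against each other at a single month, with replicate 1 at month 1 and so on to month 5. The Landrace months and Taihu months groups were loops within a breed, in which replicate 1 set month 1 against month 5 and replicates 2 to 5 set each later month against the month before it. Every RNA was on 3 arrays. Channel medians lay between 690 and 2681 intensity units over backgrounds of 99 to 564, and all 140 probes exceeded background in at least 25 of the 30 channels. The files do not pair the probes with genes, so the results describe how many probes changed, in which direction and by how much. The p-values measure only the spread between these arrays, which may be technical, since each breed and month had 1 RNA label.

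Arrays that shared an RNA gave closely related signals, apart from 1 array. For 28 channels, the mean rank correlation across probes with the same RNA elsewhere lay between 0.901 and 0.983, with Taihu months replicate 5 left out of their partners. On that array, which carried Taihu at months 5 and 4, the correlation was 0.697 in Cy3 and 0.534 in Cy5. Some of the 28 channels were closer to another RNA, such as Cy3 of Taihu versus Landrace replicate 3. It had 0.941 with Landrace month 2 and 0.901 with its own RNA, Landrace month 3. High values alone therefore do not show that a channel held the RNA of its label. The labels were also checked by comparing the change of the breed difference between 2 months on the breed arrays with the same quantity from the month arrays. Across probes r was 0.902 for months 1 and 5, 0.935 for months 2 and 1, 0.903 for months 3 and 2 and 0.844 for months 4 and 3. For months 5 and 4, which rest on the departing array, r was 0.537. Probes are not independent replicates, so these values describe the arrays only. The main counts below are therefore also given without Taihu months replicate 5.

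**Figure D1:**
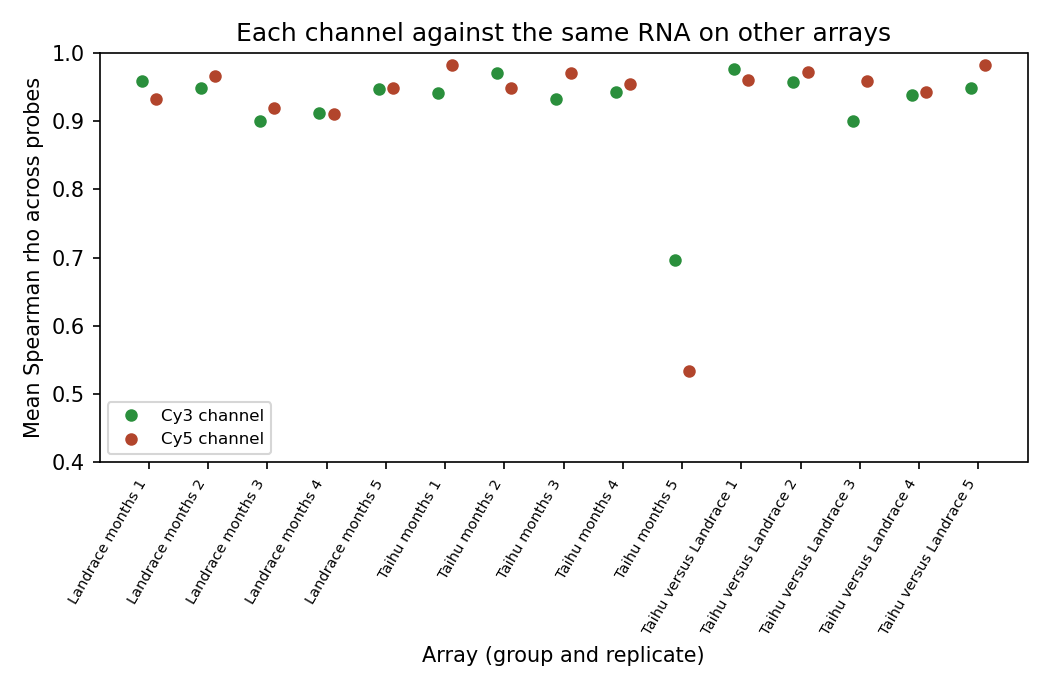
Mean Spearman rank correlation across probes (vertical axis, no unit) of each channel with the same RNA on other arrays, for the 15 arrays (horizontal axis), Cy3 in green and Cy5 in red; Taihu months replicate 5 is left out of the partners of the other arrays. The other 28 channels lie between 0.901 and 0.983, and those of Taihu months replicate 5 at 0.697 and 0.534.

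The first question was how backfat of the fat type differed from that of the lean type at the same age. At month 1, 18 probes were higher and 24 lower in Taihu than in Landrace, and at month 2 the numbers were 22 and 21. Month 3 had 10 higher and 22 lower probes, month 4 had 8 and 25, and month 5 had 10 and 8. Differences of at least 2-fold were called as lower in Taihu for 12, 13 and 9 probes at months 1, 3 and 4 and as higher for 1, 0 and 0, but 9, 10 and 9 of the lower ones were probes with saturated spots on some array. Month 2 had 6 probes at least 2-fold higher and 3 at least 2-fold lower, of which 5 and 3 had no saturated spot, and month 5 had 2 higher, neither saturated, and 0 lower. Among called probes without a saturated spot, the lowest Taihu over Landrace log2 ratios were -1.18 ± 0.30 (SE) at month 1, -1.52 ± 0.17 at month 2, -1.78 ± 0.30 at month 3, -0.84 ± 0.11 at month 4 and -0.90 ± 0.14 at month 5, with adjusted p = 0.0261, 0.00126, 0.00453, 0.0016 and 0.00297 in limma. At month 2, a probe with no saturated spot reached 2.17 ± 0.50 (adjusted p = 0.0177).

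In all, 168 breed differences at single months passed the test, 68 higher and 100 lower in Taihu, and 238 passed without Taihu months replicate 5. They fell on 82 probes (101 without that array), of which 30 were higher in Taihu at every month called, 31 lower at every month called and 21 higher at some months and lower at others (34, 32 and 35 without that array). A single probe was called at all 5 months, and 5 were without that array. Of these, 0 and 1 were called in the same direction at every month. By month, 23, 32, 16, 18 and 15 were higher and 31, 30, 29, 35 and 9 lower without that array, and at month 1 the probes at least 2-fold lower numbered 7 in place of 12. With the 19 probes that had saturated spots left out, 63 differences were higher and 63 lower. The total was 43 (20 higher and 23 lower) with the dim control level subtracted, 92 (42 and 50) without a dye term and 76 (39 and 37) from the 61 probes of the value table. The total was 111, 110 and 102 without replicates 1, 2 and 3 of Taihu versus Landrace, each of which is the direct comparison of its month. It was 128 and 159 without replicates 4 and 5 of that group. Leaving out single month arrays gave 113 to 141, apart from 237 and 238 without replicate 5 of the Landrace and Taihu loops. The fall is thus not particular to the direct comparisons.

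**Figure D2:**
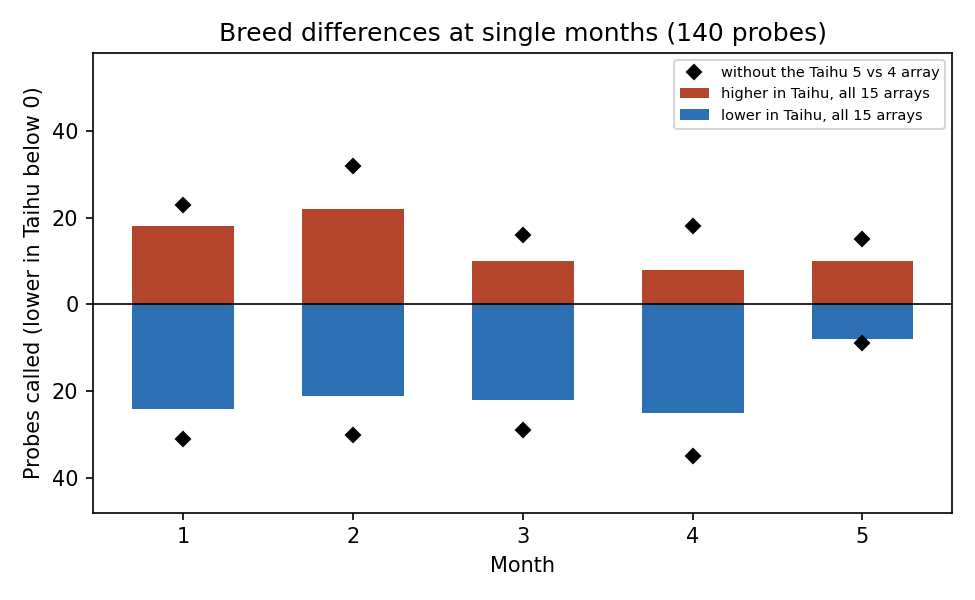
Number of probes called (vertical axis, of 140) as higher (red, upward) or lower (blue, downward) in Taihu than in Landrace at months 1 to 5 (horizontal axis); bars are from all 15 arrays and diamonds from the fit without Taihu months replicate 5. Month 2 has 22 higher and 21 lower probes, month 4 has 8 and 25, and at month 5 the numbers fall to 10 and 8.

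A difference of the same size at every month was a separate question. Averaged over the 5 months, no probe passed the test in the additive model (0 of 140 in limma, smallest adjusted p = 0.138), and 12 had an unadjusted p under 0.05. Without Taihu months replicate 5 the count was also 0, with 10 at an unadjusted p under 0.05. Of the 5 probes with the smallest p, all had negative estimates at each of the 5 months. Picking probes by the p of their mean favours estimates of the same sign, so this adds no support for a constant difference. The first of the 5 probes had a mean log2 ratio of -0.63 ± 0.15 (SE) and the next -0.42 ± 0.10, both at adjusted p = 0.138. The spread in this model includes breed differences that changed with month, and its median residual SD was 0.31, against 0.15 in the full model. With the full model's spread, the same mean passed for 25 probes, 9 higher and 16 lower in Taihu, and for 38, 14 higher and 24 lower, without Taihu months replicate 5.

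Whether the breed difference depended on month was tested directly. It did so for 78 of 140 probes (limma, moderated F over 4 terms), and for 97 without Taihu months replicate 5. It passed for 50 probes without a dye term, for 40 of the 61 in the value table and for 36 with the dim control level subtracted. The 78 called from all arrays included 74 of the 82 probes with a breed difference at some month. Of the 78 probes brighter than the dim control positions, 59 were called, and of the 62 others, 19 were (66 and 31 without Taihu months replicate 5). Breed differences at months 3 and 4 had r = 0.875 across probes (0.869 without that array), and those at months 1 and 3 had r = 0.771 (0.71). Over the 121 probes without a saturated spot these fell to 0.712 and 0.593. Months 2 and 5 stood apart. Month 2 had r = -0.133 against month 1 and -0.209 against month 3 (-0.137 and -0.282 without the array, -0.317 and -0.357 over the 121 probes). Month 5 had r = 0.0974 against month 1 and 0.0335 against month 3 (-0.0603 and -0.327 without the array, 0.0729 and 0.0925 over the 121 probes). Between months 4 and 5, r was 0.0635, and -0.386 without the array. Errors shared through the arrays would alone give r of 0.380 for adjacent months and for months 1 and 5, and 0.225 for the others.

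The second question was how expression changed over months. Changes shared by both breeds passed for 15 probes, of which 10 rose and 5 fell, and for 13 without Taihu months replicate 5. At least 15 probes were called in 39 of 100 orders of the Taihu months against the Landrace months, the real order among them. Every order keeps each breed's own changes over months and alters only which months are paired. The count therefore does not show that the breeds changed at the same months, and these orders cannot exclude chance. Of the 15, 10 also passed the test of a different course in the breeds. Among the 15, the steepest rise was that of Sr01R04C03, at 0.69 ± 0.13 (SE) log2 units per month (adjusted p = 0.0149 in limma). From month 1 to month 5 it rose by 1.94 in Landrace and 3.31 in Taihu, and the breeds differed in its course (adjusted p = 0.0001). Sr01R04C06 rose by 0.65 ± 0.12 per month (adjusted p = 0.0184), or by 2.10 in Landrace and 2.72 in Taihu between months 1 and 5, again with a different course in the breeds (adjusted p = 0.00081). In Landrace, the log2 levels over month 1 were 2.82, 2.88 and 1.94 for Sr01R04C03 at months 3, 4 and 5. For Sr01R04C06 they were 2.55, 2.91 and 2.10, so in both probes the Landrace level was lower at month 5 than at month 3. In Taihu the larger part of the rise came between months 2 and 3. At month 2 the log2 ratios of Taihu over Landrace were -1.04 ± 0.12 for Sr01R04C03 and -1.52 ± 0.17 for Sr01R04C06, both at adjusted p = 0.00126. At month 3 they were 0.20 ± 0.12 and 0.017 ± 0.17 and did not pass (adjusted p = 0.276 and 0.961). Sr01R04C03 differed again at month 4, by -0.48 ± 0.12 (adjusted p = 0.0233), and was higher in Taihu at month 5, by 1.05 ± 0.12 (adjusted p = 0.00126), while Sr01R04C06 did not pass at either month (-0.46 ± 0.17 and 0.45 ± 0.17, adjusted p = 0.0966 and 0.108). Sr01R03C04 changed by -0.30 ± 0.04 per month (adjusted p = 0.00391) and Sr02R03C03 by -0.22 ± 0.05 (adjusted p = 0.00731). Between months 1 and 5 these changed by -0.97 and -0.91 in Landrace and by -1.47 and -1.27 in Taihu, and the test of a different course gave adjusted p = 0.0557 and 0.0226. None of the 4 probes had a saturated spot, and Sr01R03C04 was not brighter than the dim control positions.

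The shared count of 15 fell to 4 without Taihu months replicate 1 and to 7 without Landrace months replicate 1, the arrays that join months 1 and 5, and was 23 without Landrace months replicate 3. The month arrays alone called 2. Without Taihu months replicate 1, Sr01R04C03, Sr01R04C06 and Sr02R03C03 kept slopes of 0.55, 0.56 and -0.19 with adjusted p = 0.0895, 0.109 and 0.0603 in limma, and Sr01R04C06 had adjusted p = 0.0557 without Landrace months replicate 1. With the dim control level subtracted, the slopes of Sr01R04C03, Sr01R04C06 and Sr01R03C04 were 1.44, 1.24 and -0.80, and Sr01R04C06 did not pass (adjusted p = 0.0862).

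**Figure D3:**
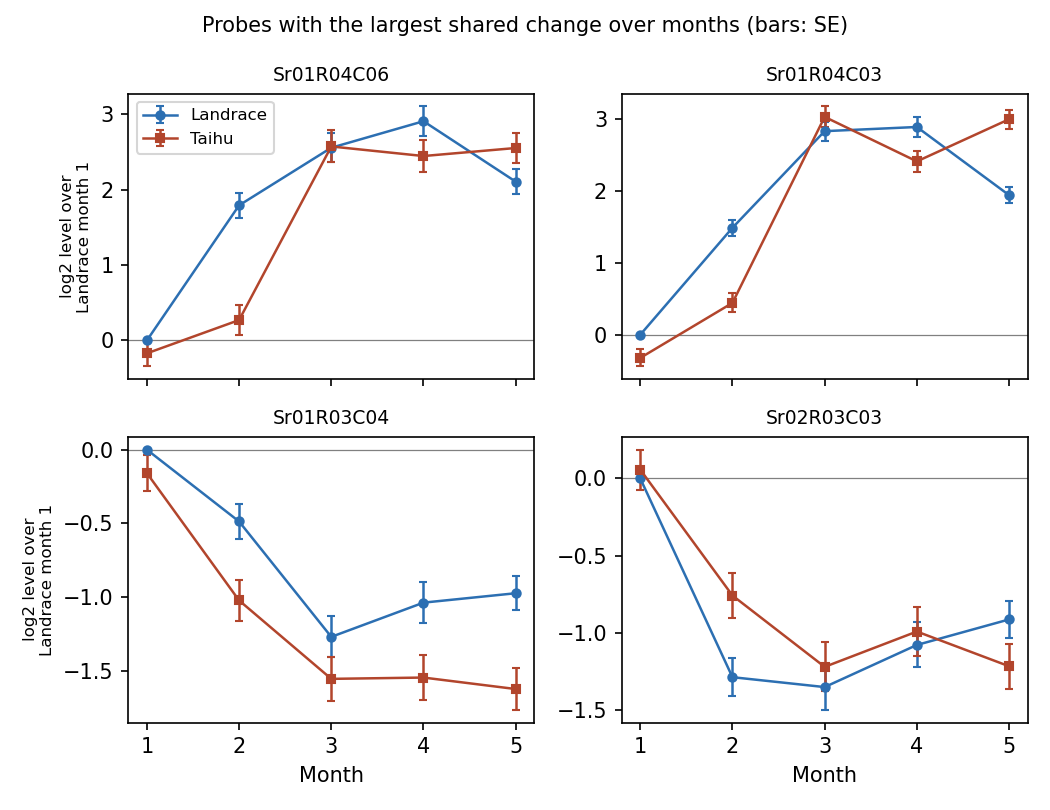
Fitted log2 level relative to Landrace month 1 (vertical axes, log2 units) at months 1 to 5 (horizontal axes) in Landrace (blue circles) and Taihu (red squares) for the 4 named probes; bars are standard errors of the full model. Sr01R04C06 and Sr01R04C03 lie above their month 1 levels from month 3 on in both breeds, and Sr01R03C04 and Sr02R03C03 below them.

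Within each breed, more probes changed over months in the full model than the shared model called. The counts rest on unlike spreads and cannot be set side by side. The median residual SD was 0.15 in the full model and 0.31 in the additive model, whose spread includes breed differences that changed with month. In Landrace 77 probes changed (92 without Taihu months replicate 5), 39 with a rising and 38 with a falling slope. In Taihu 85 changed (98 without that array), 39 rising and 46 falling. The loops alone, without a dye term, called 20 probes in Landrace and 0 in Taihu. Each loop alone leaves 1 residual degree of freedom, the sum around the loop, which holds any dye bias. In Taihu it also holds the departing array, so these counts cannot be set against each other. Of the 61 probes in the value table, 30 rose and 18 fell in Landrace and 28 and 15 in Taihu. With the dim control level subtracted, 50 and 47 were called. The median range between the highest and lowest month was 1.01 log2 units among the Landrace probes and 0.98 among the Taihu probes, and ranges of at least 1 were found for 39 and 40 of them. Landrace probes most often had their highest level at month 1 (30 of 77), and Taihu probes at month 2 (28 of 85). Both lists held 65 probes (80 without that array), where 46.75 would be shared by independent lists of these sizes, and 60 of the 65 had slopes of the same sign. The lists come from the same model and share its arrays and spread, so part of the excess over 46.75 may come from that.

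Most single steps fell on the first months. From month 1 to month 2, 26 probes rose and 28 fell in Landrace, and 32 rose and 23 fell in Taihu. For the step from month 2 to month 3, 29 rises and 42 falls were called in Taihu and 16 and 13 in Landrace (20 and 23 without Taihu months replicate 5). The difference between the breeds in these numbers was not itself tested. From month 3 to month 4, 18 probes changed in Landrace and 14 in Taihu, and from month 4 to month 5, 22 and 23. Between months 1 and 5, 68 changed in Landrace and 55 in Taihu. Sr01R04C03 rose by 2.58 ± 0.11 (SE, adjusted p = 6.92e-06 in limma) from month 2 to month 3 in Taihu. Over the 10 steps, 409 changes were called, and 504 without Taihu months replicate 5. The total was 234 without a dye term, 211 from the value table and 229 with the dim control level subtracted. Taihu months replicate 5 is the direct comparison of months 4 and 5 in Taihu. Without it, the Taihu step from month 3 to month 4 had 24 calls in place of 14, while the step from month 4 to month 5 had 22 in place of 23, of which 20 rose and 2 fell in place of 15 and 8.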

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

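The reading of the likeness between Taihu months 3 and 4 and Landrace month 5 as an earlier change in Taihu, and the reading of the month dependence with the dim control level subtracted, were chosen only after the result was seen; the other tests in this part were written down before.

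On Taihu versus Landrace replicate 2, 10 probes had saturated spots, against at most 6 on the other 4 breed arrays. Landrace months replicates 2 and 3, which also carried Landrace month 2, had 10 and 9 such probes. The number may thus go with that RNA and not with the array. Taihu months replicate 5 had the most, 14, but did not stand apart within its group. The count on Taihu versus Landrace replicate 2 was the only 1 of 15 such comparisons within groups to stand apart, and chance gives about 1 in 20. The mean rank correlation with the same RNA was also compared. At 0.615, Taihu months replicate 5 did not stand apart by this rule, with 0.833 next in its group. That value, of replicate 4, was 0.949 with replicate 5 left out of its partners.

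Both channels of Taihu months replicate 5, month 5 against month 4, departed from the same RNAs on other arrays. Saturated spots are argued against, since over the 121 probes without any the mean rank correlation with the same RNA was still 0.631. Both channels were closer to another RNA than to their own, Cy3 to Landrace month 1 (0.854) and Cy5 to Taihu month 2 (0.865). Some channels of other arrays were too, such as Cy3 of Taihu versus Landrace replicate 3. It had 0.941 with Landrace month 2 and 0.901 with its own RNA. The closest RNA therefore does not tell which RNA a channel held. The 0.854 and 0.865 lie below the 0.901 to 0.983 of the other channels with their own RNA. This argues against another of the 10 RNAs, hybridized as well as on the other arrays. A mix-up together with a fault of the hybridization, a mixture or an RNA from outside the study stays open, and no biological explanation was tested.

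The breed difference depended on month for 78 probes, found by a test of the difference between months itself. The departing array is argued against as the source, since the calls did not need it and 97 probes were called without it. The rise from 78 is not further evidence. The median residual SD fell from 0.15 to 0.12 without the array, and leaving out Landrace months replicate 5 in its place also gave 97. Calls resting mainly on dim probes are argued against as well, since 75.6% of the probes above the dim control positions were called and 30.6% of the others, although brighter probes are also easier to call. Nonspecific signal of the size of the dim control level may still contribute and stays open. With that level subtracted 36 probes were called, but the agreement of arrays that share RNA also fell, from r = 0.902 to 0.71. The subtraction therefore cannot tell such signal from added noise. Differences between the animals sampled at each month may underlie it and cannot be told apart from a breed effect, because each breed and month had 1 RNA label, and a breed effect stays open and untested.

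The Taihu RNAs of months 3 and 4 resembled Landrace month 5 more than Landrace of their own months. Across probes, centred on the mean of the 10 RNAs, Taihu month 3 had r = 0.778 with Landrace month 5, and -0.182 with Landrace month 3, and Taihu month 4 had r = 0.803 with Landrace month 5 and 0.215 with Landrace month 4. Without the departing array, which carries Taihu month 4, its r was 0.804 with Landrace month 5 and 0.427 with Landrace month 4. Saturated spots may contribute and stay open, since over probes without them r of Taihu month 3 with Landrace month 5 was 0.485, against 0.383 with Landrace month 3, and that of Taihu month 4 0.495, against 0.339 with Landrace month 4. At month 2 the likeness went the other way. Taihu month 2 had r = 0.782 with Landrace month 1 and 0.625 with Landrace month 2. Over probes without saturated spots these were 0.656 and -0.036. An earlier change in Taihu is thus a candidate explanation for months 3 and 4 only. It cannot be told apart from differences between animals, with 1 RNA label for each breed and month.

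For the mean breed difference, exchanging the breed labels at some of the months gives 16 splits, too few for a share under 0.05. The real split called 0 probes, and the highest other count was 45, with the labels exchanged at months 2 and 5. For the change shared over months, 100 of the 120 orders of the Taihu months against the Landrace months were taken. The real order was among them, and 39 of the 100 called at least its 15 probes. Every order keeps each breed's own changes over months and alters only which months are paired, so the orders cannot exclude chance. The highest other order called 49, with Landrace months 2, 1, 3, 5 and 4 set beside Taihu months 1 to 5. Such a count, several times the real one, is the highest of the orders drawn. A structure of the samples may underlie it, which was not tested.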

How the results depend on the processing

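Chosen after the results were seen were the filter on the dim control positions, leaving out probes with saturated spots, subtracting the dim control level, and the counts without Taihu months replicate 5 given beside the main counts of the report. No paired analysis was possible because the replicate numbers stand for months or pairs of months, not for shared animals, and each array already sets 2 RNAs side by side. A block for slide or scan date was not run, since the dates are empty in the files used here, nor were camera and fry, since the probes carry no gene names. Scaling between arrays and testing all probes moved nothing by construction. The 0 probes of the mean breed difference became 3 with array weights, 25 with a term for each breed and month, and 7 from the breed arrays alone with the dye left in. Calls at single months fell from 168 to 92 without a dye term, 76 from the value table (61 probes) and 43 with the dim control level subtracted. Under the same 3 settings, single steps fell from 409 to 234, 211 and 229, and the dependence on month from 78 to 50, 40 and 36. The shared month changes fell from 15 to 2 with the month arrays alone. Changes in Landrace fell from 77 to 48 from the value table, 50 with the dim level subtracted and 20 from its loop alone without a dye term. Those in Taihu fell from 85 to 43, 47 and 0 in these settings, and to 55 with the filter on the dim control positions. The value table has values on all arrays for 61 probes and the dim control filter tests 78, so fewer probes can be called and a lower count there is not a lower share. A loop alone has fewer arrays and no dye term, which were not tested apart. Its residual spread is the sum around the loop, which also holds any dye bias. For the other settings the cause was not tested. The agreement of arrays that share RNA fell from r = 0.902 to 0.71 with the dim level subtracted. Higher and lower calls moved from 68 and 100 to 39 and 37 at single months in the value table, from 39 and 38 to 30 and 18 in Landrace, from 39 and 46 to 28 and 15 in Taihu and from 202 and 207 to 134 and 77 over steps. With the dim level subtracted, shared month changes were 6 rising and 5 falling in place of 10 and 5. Without a dye term, the splits were 21 and 32 in Landrace and 19 and 39 in Taihu. With each array left out in turn, the counts ranged from 0 to 0 for the mean breed difference, 102 to 238 at single months, 4 to 23 for shared month changes, 59 to 98 in Landrace, 61 to 102 in Taihu, 308 to 571 over steps and 65 to 97 for the dependence on month. With saturated probes left out, calls at single months were 63 higher and 63 lower. The 4 named probes kept their direction in 116 of 116 combinations of probe and setting, many of which leave the slope unchanged by construction, and their call in 111; with the dim level subtracted, Sr01R04C06 was not called (adjusted p = 0.0862). Low signal over the dim control positions limits 62 probes.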

Other observations

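All comparisons in this part were chosen only after the results were seen, apart from the dye comparison.

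Steps between months were also compared between the breeds on arrays that share no RNA, the Landrace loop against the Taihu loop, with each loop's mean taken off. Across probes, r was 0.749 for months 1 and 5, 0.608 for months 3 and 2, 0.633 for months 4 and 3, 0.111 for months 2 and 1 and -0.397 for months 5 and 4, which involve the departing array. In the same order the rank correlations were 0.682, 0.403, 0.306, 0.156 and -0.231. With the dye term taken without the departing array in place of the loop means, r was 0.685, 0.577, 0.598, 0.114 and -0.186. Among the 10 RNAs, Taihu month 2 was closest to Landrace month 1 across probes (r = 0.782), and Taihu months 3 and 4 were close to each other (r = 0.840).

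The dye comparison was set before its values were seen and was first weighed as a pattern of its own; it is given here as values only. The breed arrays alone, where breed and dye go together, called 7 probes, with a median absolute log2 difference of 0.84. Once the dye term from the month arrays was fitted, the median for these 7 was 0.10, and 4 of them kept their sign. Across all probes, the mean of the breed arrays and the mean of the month arrays had r = 0.328. A set of probes that varied together was also looked for, and is not reported because its members changed between settings.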
